A study of Mus musculus with 10 samples.

How the data were processed

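Total RNA from whole retina of C57BL/6JJmsSlc mice was hybridised to 10 Affymetrix whole-transcript arrays, 2 for each of 5 groups. The groups were untreated retina at postnatal day 7, untreated retina at day 17, and 3 groups of day 17 retina with oxygen-induced retinopathy (OIR): uninjected, injected into the vitreous with phosphate-buffered saline (PBS), and injected with the inhibitor ISOX DUAL. Per the labels' protocols, RNA was extracted with Trizol, then fragmented and biotinylated with the WT Terminal Labeling Kit. The deposited table holds 1 log2 value per transcript cluster and array. The scale was read from the values, which run from 0.78 to 13.67 with array medians of 5.55 to 5.68. The software, background correction and normalization that the authors used are not given in the sources used here, and the values were not normalized again.

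The table has 72688 rows. After 6732 control rows were set aside, 65956 transcript clusters remained, of which 30604 have 1 gene symbol, 2146 have several and 33206 have none in the probe annotation used here. Symbols were updated through the Entrez identifier for 22818 clusters and through the symbol or a synonym for 7784, using RefSeq genes of GRCm38.p6, and 2 were kept as given. No genome build is named for the values, so no coordinates are printed. A gene was represented by its single-symbol cluster of highest mean (30063 genes, 429 of them with several clusters). It was tested if at least 2 arrays lay above that array's 30th percentile, which left 23255 genes. Clusters with several symbols or none were not given a gene name. Brd3 shares its cluster's annotation with a microRNA gene and is not analysed here.

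Signal over background was similar on the arrays. Between 8.00% and 9.97% of transcript clusters exceeded the 95th percentile of the array's own negative control probes, and the area under the curve separating positive from negative control probes was 0.821 to 0.863. No fold is given for a gene whose lower group lay below the median of the negative control probes on both arrays, a rule chosen after the data were seen. The log2 differences of such genes, which include Olfm4 and Mob3b in OIR and Fgf15 between the days, are not exact sizes. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.134 log2, and the median half-width of its 95% interval was 0.312 log2. The labels do not say whether the arrays of a group came from separate animals or from pools, so p-values measure the spread between these arrays, which may be technical. Across genes, the differences between the first and second arrays correlated among the 3 uninjected groups (r of 0.583, 0.809 and 0.587) and between both injected groups (0.399), and at -0.0567 to -0.406 between an uninjected and an injected group, so the numbers may reflect shared processing that the labels do not give.

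Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend) over all 10 arrays, which share 1 estimate of the spread with 5 residual and 2.76 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 23255 genes, with a threshold of 0.05. Adjusted p-values of genes are from this fit unless another setting is named, and ± gives its standard error (SE). Gene lists (33, fixed before the data were examined, with at least 5 tested members each) were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 33 lists. Camera compares a list with all other genes. Each list was tested again with a correlation estimated from its own members and with fry, which asks whether the members move together in 1 direction. List counts adjusted over the list alone apply the Benjamini-Hochberg method to the members only. The comparisons, lists, named-gene rule and most of the other settings were chosen before the data were examined.

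Genes were named by a fixed rule. In each comparison it took up to 10 genes of largest log2 difference in each direction among those past the threshold whose groups did not overlap, leaving out predicted and unnamed genes. Where fewer than 5 passed in a direction, the genes of smallest p filled the places and are stated as not past the threshold. It added up to 4 members of smallest p from each list described, a fixed set (Vegfa, Epo, Gfap, Edn2, Esm1, Apln, Angpt2, Serpina3n, Brd2, Brd3, Crebbp, Ep300, Myc and Hexim1, with items withheld from this text left out), and up to 10 genes raised in OIR and lower with the inhibitor, or the 5 of smallest larger p where none passed.

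The steps were tested on simulated data with 200 changed genes among the 23255. For ISOX DUAL against PBS, 80.0% of 2-fold changes, 96.5% of 4-fold changes and 0.5% of 1.5-fold changes were recovered. For uninjected OIR against untreated retina the shares were 72.5% at 2-fold and 98.0% at 4-fold. The simulation drew the spread of each gene independently, so it does not hold the correlation between genes that the arrays show. It also changed all 200 genes by the same size, which eases the adjusted threshold. Recovery would be lower where few genes change, so the shares do not rule out 2-fold differences in the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading tables and drawing. Alternatives covered the filter on level, several clusters per gene, quantile normalization, median centring, the eBayes options, array weights, the arrays in the fit, the replicate number as a block, the threshold and each array left out in turn. Chosen only after the data were seen were the fit of the day 17 groups alone, the test over protein-coding genes, crossed replicate numbers (those of the injected groups swapped), both injected groups taken against uninjected OIR, and PBS-injected OIR taken against untreated retina.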

Results

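Retinal transcripts were measured in a mouse model of ischaemic retinopathy. In OIR, mouse pups breathe 75% oxygen from postnatal day 7 for 5 days, which halts and prunes the growing retinal vessels. On return to air the poorly perfused retina becomes hypoxic, and new vessels sprout by day 17. The injected groups received PBS or ISOX DUAL, known as a bromodomain inhibitor, at the end of hyperoxia. Each of the 5 groups has 2 arrays. The series describes a search for genes that rise in OIR and return toward the untreated level with the inhibitor, so uninjected OIR was first compared with untreated day 17 retina, and the inhibitor then with PBS and with uninjected OIR.

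Uninjected OIR retina at day 17 showed higher transcripts of hypoxia, vessel-sprouting and glial-reactivity genes than untreated retina of the same day (n = 2 arrays per group). Adm, which encodes the vasoactive peptide adrenomedullin, rose (log2 difference 3.23 ± 0.19, adjusted p = 0.00392), and Serpina3n, a marker of reactive glia, rose 8.21-fold (3.04 ± 0.35, adjusted p = 0.0191). Among endothelial tip cell genes, Angpt2 rose 3.65-fold (1.87 ± 0.13), and Apln (2.44 ± 0.19) and Esm1 (1.60 ± 0.19) rose. In untreated retina Adm (5.39), Apln (5.16) and Esm1 (5.11) lay below the median of the negative control probes (5.84) on both arrays, so the sizes of their rises are not exact and no folds are given. The intermediate filament gene Gfap rose 5.26-fold (2.39 ± 0.18). Vegfa, the main hypoxia-driven vessel growth factor, rose 2.12-fold (1.08 ± 0.12, adjusted p = 0.0176), and Edn2 rose 1.98-fold (0.99 ± 0.11).

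In all, 115 of 23255 genes passed the limma threshold, 106 higher and 9 lower in OIR. Other raised genes were Hmox1 (heme oxygenase 1, 5.77-fold), Fgf2os (2.50 ± 0.34 log2, from 4.57 in untreated retina, also below that median), Egln3 (a prolyl hydroxylase of hypoxia-inducible factor, 5.61-fold), Ndufa4l2 (4.91-fold), Fn1 (fibronectin, 4.02-fold) and Ccn1 (3.83-fold). Of the 9 lower genes Folh1 had the largest fall, by 1.84 on the log2 scale (± 0.25, adjusted p = 0.0306). Spc25, a kinetochore gene also known as a marker of Müller glia, fell by 1.71 (± 0.14), and Olfm4 (-1.32 ± 0.13), Abca8a (-0.87 ± 0.12), Cdcp3 (-0.80 ± 0.12), Mob3b (-0.65 ± 0.10) and Deptor (-0.58 ± 0.09) fell too. Epo, encoding erythropoietin, was 0.95 ± 0.17 log2 higher without passing the threshold (adjusted p = 0.0797). Myc (0.44 ± 0.12), Brd2 (0.11 ± 0.16), Hexim1 (-0.33 ± 0.15), Crebbp (-0.01 ± 0.20) and Ep300 (-0.06 ± 0.35) did not pass either. The count rests on single arrays: it was 3 without the first and 0 without the second untreated array, and 6 without the first and 35 without the second OIR array. Arrays of the other groups enter through the shared spread, and the count was 23 without either ISOX DUAL array, 54 without either PBS array and 84 without either day 7 array. It was 0 with only these 4 arrays in the fit and 12 with array weights.

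The fixed gene lists moved in groups. Of 22 tested tip cell genes, all had a positive difference (median 0.68 log2), 7 rose over all genes tested and 20 rose when adjusted over the list alone (camera adjusted p = 1.73e-40). Of 31 targets of hypoxia-inducible factor, 9 rose over all genes, among them Egln1 (1.94-fold), and 23 rose and 1 fell when adjusted over the list alone (median 0.69 log2, camera adjusted p = 1.56e-38). Of 23 reactive Müller glia genes, 11 rose over all genes and 15 when adjusted over the list alone (median 0.95 log2), including A2m (3.69-fold), the transcription factor genes Stat3 (2.96-fold) and Cebpd (3.52-fold), and Gfap. Extracellular matrix genes (4 of 21 over all genes, 11 adjusted over the list alone; Thbs1 2.30-fold, Tgfbi 1.75-fold), angiogenic factors and receptors (7 of 25, 9 higher and 1 lower adjusted over the list alone) and immediate-early genes (1 of 20, Atf3 at 1.84-fold, 9 adjusted over the list alone) rose too. Pericyte and smooth muscle genes rose as a list with 0 of 15 members past the threshold over all genes and 6 adjusted over the list alone, the smallest p being that of Rgs5 (0.96 ± 0.17 log2, adjusted p = 0.0759). These 7 lists kept their call with an estimated correlation, at adjusted p of 0.0113 for tip cells, reactive Müller glia and angiogenic factors, 0.0116 for hypoxia targets, 0.0140 for matrix and pericytes, and 0.0389 for immediate-early genes.

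A further 14 lists were called by camera only with the preset correlation. Among these, glycolysis genes were higher (median 0.43 log2; Pfkp 1.88-fold; adjusted p = 0.125 with an estimated correlation), as were cell cycle genes (0.21 log2 over 28 genes, 0 past the threshold; adjusted p = 0.233 with an estimated correlation) and microglia and macrophage genes (0.245 log2 over 20 genes, 0 past the threshold; adjusted p = 0.223 with an estimated correlation). Homeostatic Müller glia genes were lower (-0.36 log2), with Spc25 and Abca8a past the threshold and the glial transcription factor gene Sox9 rising 1.88-fold (adjusted p = 0.125 with an estimated correlation). Retinal ganglion cell genes were lower by a median of -0.24 log2 (adjusted p = 0.599 with an estimated correlation) and bipolar cell genes by -0.27 log2 (adjusted p = 0.549 with an estimated correlation), and none of their members passed. Without the second untreated array 13 lists were called in place of 21, and the homeostatic Müller glia, bipolar and ganglion cell lists were among those lost (mean differences -0.20, -0.25 and -0.22 log2). The mean of the glycolysis list, 0.41, was 0.17 without the first and 0.64 without the second untreated array. That of the microglia list, 0.29, was 0.08 without the first and 0.50 without the second OIR array, and that of the ganglion cell list, -0.24, was -0.14 without the second OIR array. Endothelial genes were higher by a median of 0.19 (adjusted p = 0.118 with an estimated correlation), with a mean of 0.14, or 0.05 without the first OIR array. Rod genes had a median of -0.06 log2 and were not called (adjusted p = 0.804). Arrays of 1 group differed in small nucleolar RNA signal, whose mean over 62 genes was 7.31 and 8.30 log2 on the untreated day 17 arrays and 7.78 and 8.36 on the OIR arrays.

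**Figure D1:**
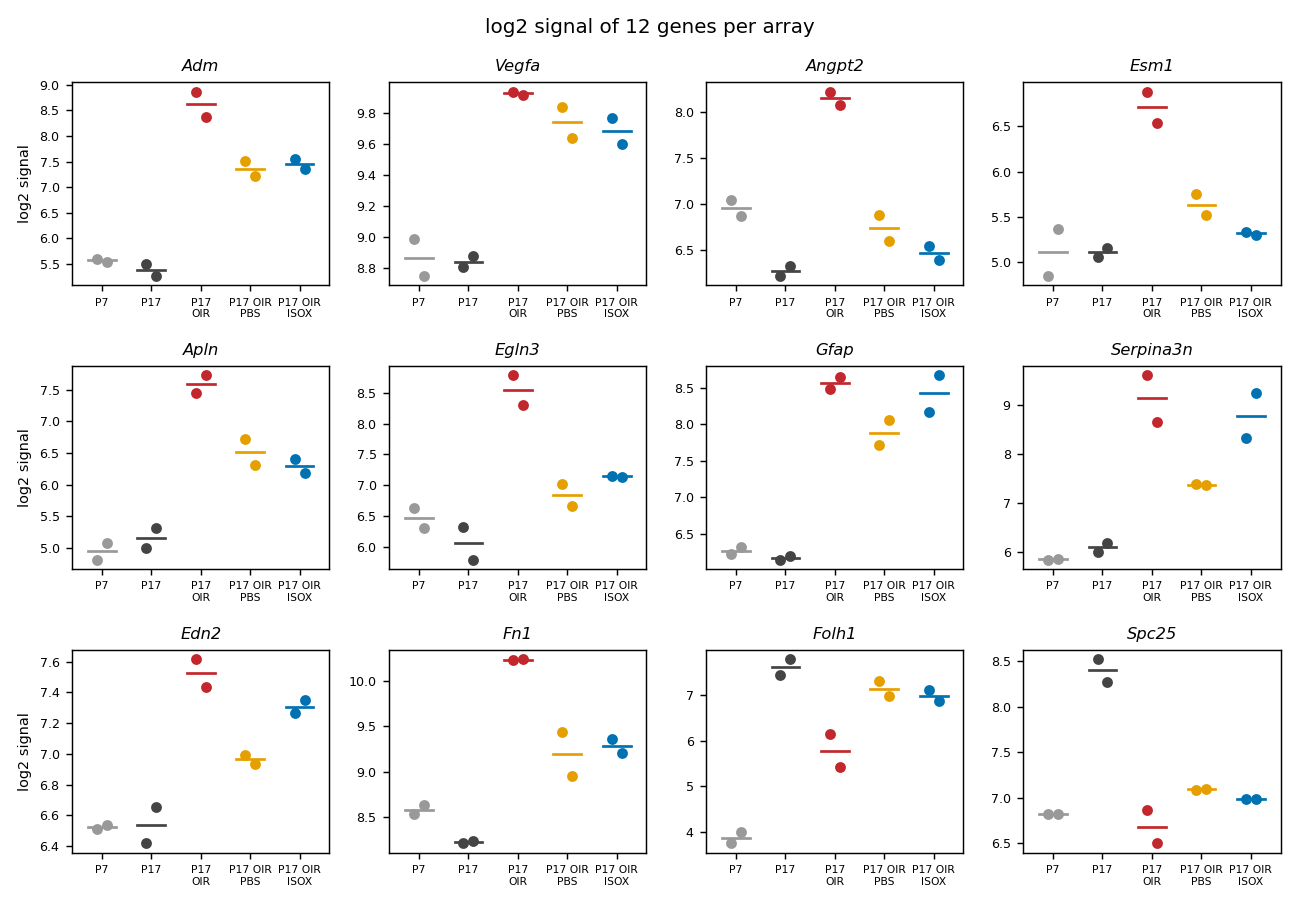
log2 signal (vertical axes, 1 scale per gene) of 12 genes in each of the 5 groups along the horizontal axis; each point is 1 array and each bar the mean of 2 arrays. Adm, Angpt2, Esm1, Apln, Egln3 and Fn1 are highest in uninjected OIR and lie lower on all 4 injected arrays, while the PBS and ISOX DUAL means of Adm are 7.36 and 7.45.

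No gene separated ISOX DUAL from PBS at the limma threshold, with both groups having OIR and an injection (n = 2 arrays per group). Of the angiogenic genes raised in OIR, Vegfa differed between the 2 groups by -0.06 log2 (95% interval -0.33 to 0.22), Apln by -0.22 (-0.65 to 0.22), Angpt2 by -0.27 (-0.57 to 0.02) and Esm1 by -0.32 (-0.75 to 0.12). Esm1 lay below the negative control medians in both groups (means 5.64 with PBS and 5.32 with ISOX DUAL), so its difference is not an exact size. The other raised members of the angiogenic list were Fgf2 (0.71 ± 0.26), Pgf (0.15 ± 0.11), Adm (0.09 ± 0.19) and Thbs1 (-0.17 ± 0.16), and the list had a median of -0.002 with 12 of 25 positive (adjusted p = 0.751). Epo, which had not passed in OIR, differed by 0.19 (-0.20 to 0.58). Of the reactive Müller glia list, Serpina3n (1.42 ± 0.35 log2, 2.67-fold), Gfap (0.54 ± 0.18) and Edn2 (0.34 ± 0.11) had higher values with the inhibitor, all at an adjusted p of 1. Brd2, Myc, Hexim1, Crebbp and Ep300 differed by 0.07 log2 or less. Myc is a gene known to respond to bromodomain inhibitors. It was at 5.53 log2 with PBS and 5.57 with ISOX DUAL. The negative control medians of these arrays were 5.99 to 6.11, so a change in Myc could have been missed.

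At an unadjusted p under 0.05, limma gave 237 genes, fewer than the 1163 expected by chance. Arrays of the same injected group differed less than arrays of the uninjected groups did: the SD of the difference between both arrays of a group was 0.16 log2 for ISOX DUAL and 0.22 for PBS, against 0.33 for uninjected OIR, 0.34 for untreated day 17 and 0.40 for day 7. With only these 4 arrays in the fit, 0 genes passed and 710 had an unadjusted p under 0.05, and with array weights the numbers were 0 and 873. Genes of smallest p, none past the threshold, were Speer4e (-0.75 ± 0.16 log2), Niban1 (-0.57 ± 0.14), Optc (-1.10 ± 0.26, opticin), Foxs1 (-0.34 ± 0.08) and Orly (-1.35 ± 0.37) lower, and Serpine3 (1.22 ± 0.29), Serpina3n, Pcolce (0.52 ± 0.13), Cryge (0.51 ± 0.14) and Scgb1b12 (0.30 ± 0.08) higher. Speer4e and Foxs1 lay below the negative control medians in both groups, so their differences are uncertain. Leaving out the first ISOX DUAL array made the lens crystallin gene Crybb1 higher by 2.50 log2.

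Reactive Müller glia genes were the 1 list to rise with ISOX DUAL against PBS that kept its call with an estimated correlation (median 0.36 log2, 20 of 23 positive, adjusted p = 7.94e-20, and adjusted p = 0.0445 with an estimated correlation). No member passed, over all genes or adjusted over the list alone, and fry gave an adjusted p of 0.253. Lens genes rose most (median 0.66 log2 over 21 genes; adjusted p = 0.330 with an estimated correlation). Complement (median 0.17 log2), microglia and macrophage (0.14), inflammatory cytokine (0.05) and hypoxia target (0.06) genes rose by the preset test, at adjusted p with an estimated correlation of 0.195, 0.484, 0.393 and 0.624. Retinal ganglion cell (-0.19), endothelial tip cell (-0.11), endothelial (-0.05) and retinal pigment epithelium (-0.105) genes fell by it, at adjusted p with an estimated correlation of 0.393, 0.393, 0.393 and 0.585. Lens signal was uneven between the ISOX DUAL arrays: the crystallin gene Cryaa was at 8.05 and 11.75 log2 there, and at 7.30 and 8.34 on the PBS arrays. Without the second ISOX DUAL array, 5 lists were called in place of 10, and the mean difference of reactive Müller glia genes was 0.29 in place of 0.395 log2, that of lens genes 0.21 in place of 0.84 and that of microglia genes 0.06 in place of 0.14. The calls of the tip cell, endothelial and inflammatory lists (means -0.12, -0.09 and 0.07) were lost without that array (-0.05, -0.05 and 0.05) and without the first PBS array (-0.04, -0.04 and 0.03). The mean of the ganglion cell list changed from -0.25 to 0.02 without the second PBS array, and that of the retinal pigment epithelium list from -0.10 to 0.06 without the first ISOX DUAL array. The hypoxia target list, at a mean of 0.06, was at 0.003 without the second PBS array and 0.0004 without the first ISOX DUAL array.

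Both injected groups had lower values than uninjected OIR for genes raised in OIR, with PBS as well as with the inhibitor. Over the 106 raised genes, the median difference from uninjected OIR was -0.68 log2 with PBS (106 of 106 negative) and -0.55 with ISOX DUAL (105 of 106 negative). The 2 injected groups stood at a median of 0.43 log2 (PBS) and 0.49 log2 (ISOX DUAL) above untreated retina, against 1.07 for uninjected OIR. Angpt2 was lower with ISOX DUAL than in uninjected OIR, where it fell by 1.68 on the log2 scale (± 0.13, adjusted p = 0.0339), and it was the single gene to pass. With PBS its difference was -1.41 ± 0.13 log2, which did not pass (adjusted p = 0.0880), but did with quantile normalization (adjusted p = 0.0491) and the replicate number as a block (0.0455), and with crossed numbers (0.0323) and over protein-coding genes (0.0338), both chosen after the data were seen. The Angpt2 calls therefore do not separate the inhibitor from PBS. Egln3 differed from uninjected OIR by -1.70 log2 with PBS and -1.40 with ISOX DUAL, Ccn1 by -1.65 and -1.68, Apln by -1.08 and -1.30, Adm by -1.25 and -1.17 and Vegfa by -0.19 and -0.24, none past the threshold. With the replicate number as a block Egln3 passed with PBS (adjusted p = 0.0455), and with crossed numbers Apln passed with PBS (adjusted p = 0.0323) and with ISOX DUAL (adjusted p = 0.0123). Serpina3n differed by -1.77 with PBS and -0.35 with ISOX DUAL, and Gfap by -0.68 and -0.14.

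By the limma threshold used here, genes raised in OIR and lower with ISOX DUAL numbered 0 with PBS as the control. With uninjected OIR as the control there was 1, Angpt2. These counts depend on that threshold and are not the series' own selection. Independent lists of these sizes would share 0.0046 genes in the second case, and simulations that kept the OIR effects and gave injected retina no change gave a mean of 0.02 and at most 1. The same simulations gave a median of -0.05 log2 for raised genes, at lowest -0.07, since the OIR arrays enter both comparisons. They called a mean of 287.5 raised genes against the 106 observed, so the selection was not the same. They also drew the arrays independently, without the correlated array differences that the data show. With 106 genes ranked on the first arrays and measured on the second, medians were -0.49 log2 for PBS (68.9% of genes lower) and -0.24 for ISOX DUAL (62.3%). With the arrays exchanged they were -0.70 (98.1%) and -0.62 (95.3%). With PBS the raised genes already stood at a median of 0.43 log2 above untreated retina, less than a 1.5-fold difference. In simulated data 0.5% of 1.5-fold changes were recovered for ISOX DUAL against PBS. A full return from the PBS level would therefore seldom pass for many of these genes. The count of 0 cannot by itself decide whether they returned, but their median stood at 0.49 log2 with ISOX DUAL. Of the raised genes, 31 of 106 were lower with ISOX DUAL than with PBS. Across the 115 genes, which are not independent replicates, the slope of the inhibitor's difference from PBS on the OIR difference was 0.14 (r = 0.46). It was 0.03 with array weights, 0.09 without the second ISOX DUAL array (over the 23 genes then called) and 0.23 without the first PBS array (over 54 genes), and it was not computed without either untreated array or the first OIR array, where fewer than 10 genes passed. Taking the larger of the p-values of both comparisons, the 5 genes of smallest p with a higher value in OIR and a lower one with ISOX DUAL than PBS were Niban1 (-0.57 ± 0.14 log2 against PBS), Olfml2a (-0.39 ± 0.15), Nid2 (-0.21 ± 0.08), Fbn2 (-0.35 ± 0.14) and Dse (-0.26 ± 0.11). None passed the threshold against PBS, and of the 5 only Nid2, encoding a basement membrane protein, passed in OIR. Dse lay below the negative control medians with PBS and with ISOX DUAL.

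**Figure D2:**
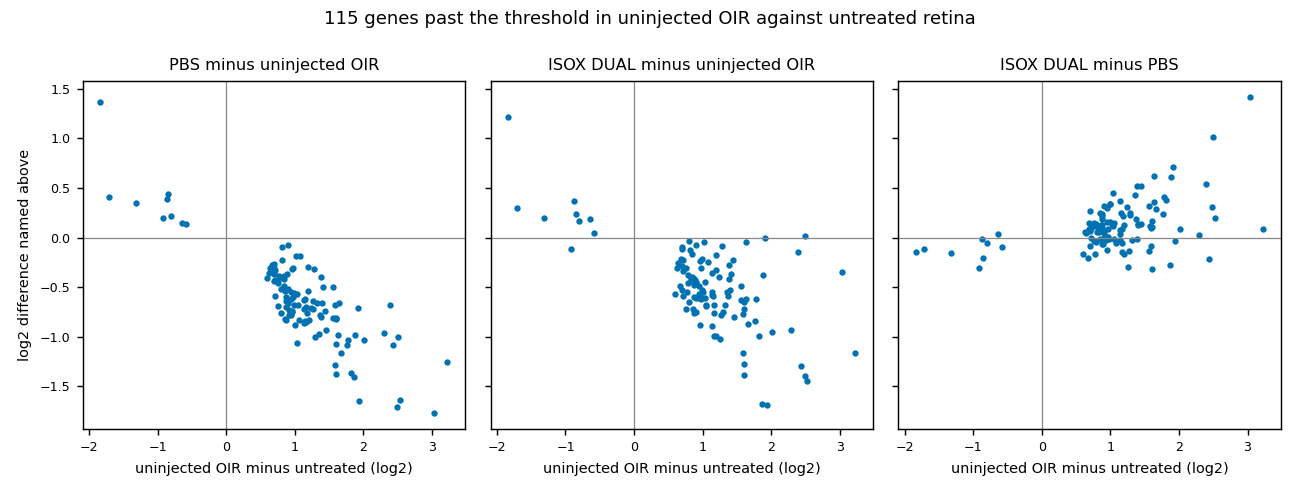
Each point is 1 of the 115 genes past the threshold in uninjected OIR against untreated retina; the horizontal axis is that log2 difference and the vertical axes are the log2 differences of PBS from uninjected OIR, ISOX DUAL from uninjected OIR and ISOX DUAL from PBS. The raised genes lie below 0 in the PBS panel (106 of 106), and their median is 0.10 in the panel of ISOX DUAL against PBS.

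For PBS against uninjected OIR, limma called 0 genes, with 997 at an unadjusted p under 0.05, and for ISOX DUAL against uninjected OIR it called 1, with 998. Genes of smallest p with PBS, none past the threshold, were Angpt2, Spidr (-1.28 ± 0.12 log2), Egln1 (-0.74), Ipo5 (-0.84) and Dusp16 (-0.69) lower, and Folh1 (1.36 ± 0.25), Bsph1 (0.90), Tmem255b (0.73), Eif2ak2 (0.54) and Mdrl (0.59) higher. With ISOX DUAL they were Spidr (-1.16 ± 0.12), Dusp16 (-0.72), Nox4 (-0.99) and Kit (-0.76) lower, and Crygb (2.67 ± 0.45), Cryga (1.27), Folh1 (1.21), Bsph1 (1.00) and Cryge (0.81) higher. Of these genes, Bsph1, Mdrl and Nox4 lay below the negative control medians in both groups compared, so their differences are uncertain. The Angpt2 call against uninjected OIR ended with any 1 of the 10 arrays left out: 0 genes passed, except that without the first ISOX DUAL array 7 passed, all crystallin genes. With the replicate number as a block, 5 genes were lower with PBS, and 2 (Angpt2 and Spidr) were lower with quantile normalization.

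Tip cell genes fell in both injected groups against uninjected OIR, by a median of -0.38 log2 with PBS (0 of 22 past the threshold over all genes, 11 adjusted over the list alone) and -0.48 with ISOX DUAL (1 of 22, 14 adjusted over the list alone). Angiogenic factors fell by -0.15 with PBS and -0.13 with ISOX DUAL, and pericyte genes by -0.15 in both. These 3 lists kept their call with an estimated correlation, at adjusted p of 0.0467, 0.0345 and 0.0368 with PBS and 0.0278, 0.0267 and 0.0267 with ISOX DUAL. Endothelial genes in general fell too, by -0.11 and -0.13 (adjusted p = 0.312 and 0.116 with an estimated correlation), and the PBS call ended without the first OIR array (mean -0.05) or the second PBS array (-0.10). The endothelial mean with ISOX DUAL, -0.23, also depended on the first OIR array. Relative to untreated retina, endothelial scores were 0.24 and 0.05 in uninjected OIR and -0.05 and -0.13 with ISOX DUAL. Reactive Müller glia genes fell with PBS by -0.68 log2 (11 of 23 adjusted over the list alone; adjusted p = 0.0345 with an estimated correlation) and with ISOX DUAL by -0.335 (5 of 23; adjusted p = 0.0882 with an estimated correlation; mean -0.28, or -0.10 without the first OIR array). Immediate-early genes fell by -0.45 and -0.40 (adjusted p = 0.0584 and 0.0744 with an estimated correlation), with Fos at -1.51 and -1.57 and Nr4a1 at -1.62 and -1.45, neither past the threshold. With crossed replicate numbers, chosen after the data were seen, Nr4a1 passed in limma with PBS (adjusted p = 0.0323) and with ISOX DUAL (adjusted p = 0.0397). Hypoxia targets fell by -0.30 and -0.24 (adjusted p = 0.0910 and 0.116 with an estimated correlation). Glycolysis genes fell by -0.38 and -0.30 (0 of 16 positive in either; adjusted p = 0.188 and 0.146 with an estimated correlation). Retinal ganglion cell genes fell by -0.28 with PBS and -0.445 with ISOX DUAL (0 of 15 positive in either; adjusted p = 0.476 and 0.146 with an estimated correlation), and the PBS call ended without the first PBS array (mean -0.04). Rod genes had medians of 0.03 and 0.07 log2 and were not called. Lens genes were higher in both, by 0.22 and 0.93 log2 (adjusted p = 0.659 and 0.146 with an estimated correlation), the mean with ISOX DUAL being 1.17, or 0.54 without its second array, and small nucleolar RNA signal averaged 9.19 and 8.49 on the PBS arrays and 8.55 and 8.44 on the ISOX DUAL arrays.

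**Figure D3:**
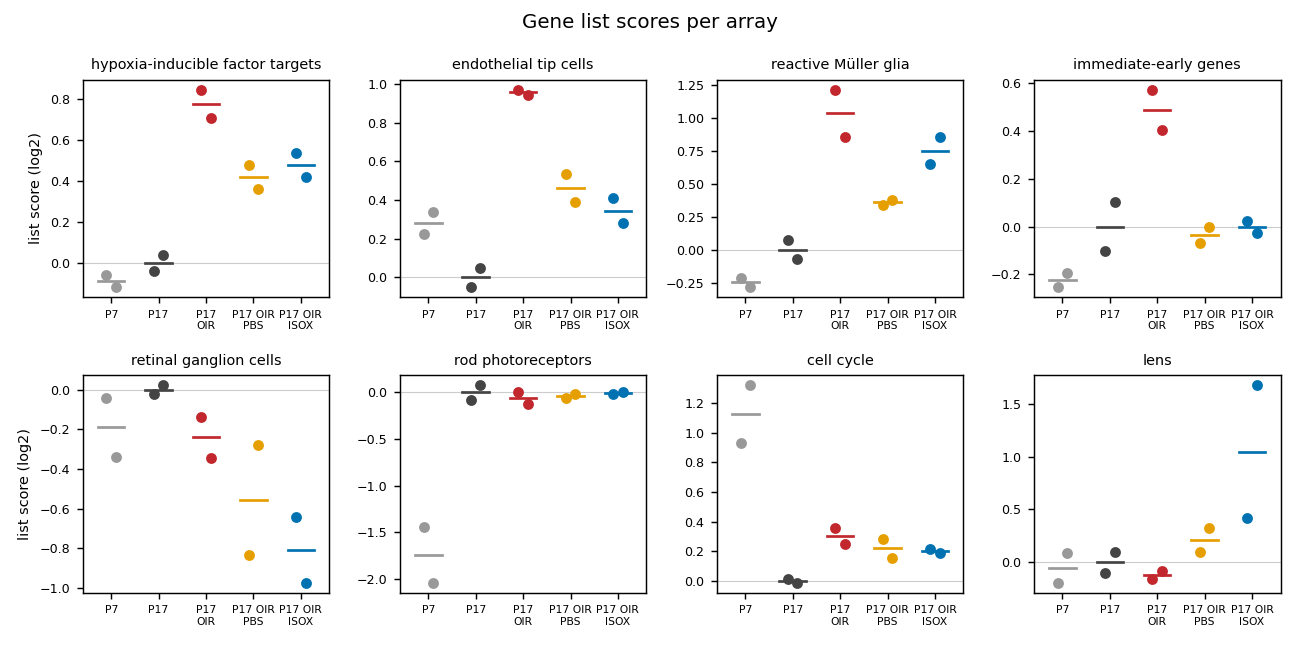
Mean log2 signal of the tested members of 8 gene lists (vertical axes, relative to the mean of both untreated day 17 arrays, 1 scale per list) in each of the 5 groups; points are arrays and bars are means of 2 arrays. Tip cell scores are 0.97 and 0.94 in uninjected OIR and between 0.28 and 0.54 on the injected arrays, and the lens score is 1.68 on the second ISOX DUAL array.

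With ISOX DUAL, Gfap and Adm were still higher than in untreated retina of the same day and Spc25 was lower. Gfap rose 4.76-fold (2.25 ± 0.18 log2, adjusted p = 0.0411), Adm rose by 2.06 (± 0.19, adjusted p = 0.0477, from below the negative control median in untreated retina) and Spc25 fell by 1.42 on the log2 scale (± 0.14, adjusted p = 0.0477). The predicted gene Gm20026, outside the rule for names and given because the count is small, fell by 1.04. These were the 4 genes to pass, with 1967 at an unadjusted p under 0.05. Not past the threshold were Pcolce (1.21 ± 0.13), Myof (0.97 ± 0.10), A2m (1.51 ± 0.17), Serpina3n (2.69 ± 0.35), Vegfa (0.84 ± 0.12), Edn2 (0.77 ± 0.11) and Epo (0.67 ± 0.17) with higher values, and Olfm4 (-1.13 ± 0.13), Frmpd4 (-0.76 ± 0.09), Ano3 (-1.43 ± 0.17) and Xlr3a (-1.14 ± 0.17) with lower ones. Xlr3a lay below the negative control medians in both groups. Angpt2 (0.19 ± 0.13) and Esm1 (0.21 ± 0.19) lay near the untreated level. The Angpt2 mean was 6.275 in untreated retina, 6.74 with PBS and 6.47 with ISOX DUAL. For Esm1 the means were 5.11, 5.64 and 5.32 in the same order, all below the negative control medians of their arrays. Its nearness to the untreated level is therefore not informative. Without the first or the second untreated array the count was 1 and 0, without the second ISOX DUAL array it was 0 and without the first it was 6, and without either day 7 array it was 0. It was 3 without either OIR array and 2 without either PBS array. With the replicate number as a block or with quantile normalization, 2 genes passed, Adm and Gfap, and with median centring 1, Gfap, so the Spc25 call was lost in each. The count was 53 with crossed replicate numbers, an alternative chosen after the data were seen. The PBS means of Gfap (7.89), Adm (7.36) and Spc25 (7.10) lay on the same side of untreated retina (6.17, 5.39 and 8.40). The ISOX DUAL means were 8.42, 7.45 and 6.98, so these differences are not particular to the inhibitor, although 0 genes passed for PBS against untreated retina.

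Of the gene lists, 15 differed between ISOX DUAL and untreated retina by camera's preset test, and 0 kept the call with an estimated correlation. Hypoxia targets were higher by a median of 0.40 log2 (16 of 31 adjusted over the list alone; adjusted p = 0.140 with an estimated correlation) and reactive Müller glia genes by 0.57 (14 of 23; adjusted p = 0.0776 with an estimated correlation). Complement genes were higher by 0.41 (6 of 12 adjusted over the list alone, 0 over all genes; adjusted p = 0.171 with an estimated correlation), C4b having the smallest p (1.26 ± 0.16 log2). Retinal ganglion cell genes were lower by -0.81 (10 of 15 adjusted over the list alone, 0 over all genes; adjusted p = 0.246 with an estimated correlation). They include the neurofilament genes Nefl (-1.50 ± 0.36) and Nefh (-0.81 ± 0.18) and the glutamate transporter gene Slc17a6 (-1.51 ± 0.37). Lens genes were higher by 0.77 here too (adjusted p = 0.349 with an estimated correlation; mean 1.05, or 0.42 without the second ISOX DUAL array).

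Between day 7 and day 17 the untreated retina gained photoreceptor and bipolar cell transcripts and lost those of dividing cells (n = 2 arrays per day). The cone opsin gene Opn1mw rose by 5.44 on the log2 scale (± 0.30, adjusted p = 0.000102), the rod exchanger gene Slc24a1 26.8-fold (4.74 ± 0.20), the rod transducin gene Gnat1 15.9-fold (3.99 ± 0.35) and the rod phosphodiesterase gene Pde6a 13.2-fold (3.73 ± 0.28). Mki67, a marker of dividing cells, fell by 4.32 on the log2 scale (± 0.30, adjusted p = 0.000310), and Mybl1 (-3.61), the progenitor and glial gene Fabp7 (-3.52), Tubb2b (-3.08), Top2a (-3.02), Ccdc175 (-2.95), Gje1 (-2.91), Cd24a (-2.71) and Myb (-2.66) fell too. Pdzph1 (4.80 log2), Lrtm1 (4.29), Abca8a (4.06) and Folh1 (3.75) rose as well. Xist fell by 7.16 on the log2 scale, and the Y-linked genes Eif2s3y and Uty rose (4.65 and 4.39 log2). Opn1mw (5.7), Pdzph1 (4.54), Lrtm1 (5.84), Abca8a (4.94), Folh1 (3.87), Eif2s3y (3.68) and Uty (4.10) at day 7, and Xist (4.56), Mki67 (4.82), Top2a (4.56), Ccdc175 (3.88) and Gje1 (5.32) at day 17, lay below the negative control median on both arrays (means of 6.02 and 5.84), so the sizes of these differences are not exact. The arrays of the 2 days therefore also differ in the transcripts that mark sex.

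Of the 23255 genes, 2454 passed, 1223 higher and 1231 lower at day 17. The count was 1500 without the second day 7 array, 1111 with array weights and 345 with only these 4 arrays in the fit. Of 18 rod genes 15 rose over all genes, and 16 rose and 1 fell adjusted over the list alone (median 1.24 log2). Bipolar cell genes (10 of 17, 15 adjusted over the list alone; Trpm1 3.40 ± 0.38, Cabp5 2.52 ± 0.20), cone genes (10 of 15, 10 higher and 1 lower adjusted over the list alone) and endothelial genes (7 of 20, 11 adjusted over the list alone; Ptprb 1.46 ± 0.11) rose. Cell cycle genes fell (20 of 28, 25 adjusted over the list alone, median -0.76 log2), as did progenitor genes (7 of 16 lower and 1 higher, 9 and 1 adjusted over the list alone; Fgf15 -1.86 ± 0.13, Notch1 -1.50 ± 0.20). Of the 11 lists called, 0 kept the call with an estimated correlation, at adjusted p of 0.231 for cell cycle, rod, bipolar, cone and endothelial genes and 0.350 for progenitor genes. Angpt2 fell by 0.68 on the log2 scale (± 0.13, adjusted p = 0.0146), while Vegfa, Gfap, Epo, Edn2, Esm1, Apln and Serpina3n did not pass.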

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

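The tests of dilution, of a crystallin response and of sex were chosen after the result was seen. The tests of small non-coding RNA signal, of separate handling and of lens carry-over were set before.

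Transcript clusters without a single gene symbol were outside the comparisons of named genes. In a limma fit of the same design, adjusted over 25138 such clusters, 6 were higher in uninjected OIR than in untreated day 17 retina and 0 were lower, with 926 at an unadjusted p under 0.05.

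Hypoxia target and tip cell genes had lower values in both injected groups than in uninjected OIR (median -0.36 log2 over 52 genes, 95% bootstrap interval over genes -0.46 to -0.24). The bootstrap intervals in this section resampled genes with the arrays held fixed. They leave out the spread between the 2 arrays of a group and treat correlated genes as independent. With an estimated correlation, camera called the tip cell list (adjusted p = 0.0467 with PBS and 0.0278 with ISOX DUAL). It did not call the hypoxia targets (0.0910 and 0.116). The arrays differed in small nucleolar RNA signal, but with each array's mean of it as a covariate the median was -0.425 (-0.52 to -0.25), which argues against that signal as the whole cause. Dilution by lens or other tissue would lower photoreceptor and bipolar cell genes alike, and their median was 0.009 (interval -0.01 to 0.07 over 50 genes). This argues only against an equal loss of all retinal transcripts. Lens scores were 0.42 and 1.68 on the ISOX DUAL arrays, yet rod scores were -0.02 and 0.01 and bipolar scores -0.26 on both. The photoreceptor and bipolar lists therefore did not register that lens signal, and a smaller share of other tissue could be missed. Retinal ganglion cell genes had a median of -0.445 with ISOX DUAL against uninjected OIR. Relative to untreated retina their scores were -0.83 and -0.28 with PBS and -0.14 and -0.34 in uninjected OIR. A smaller share of inner retina on the injected arrays was not tested. Separate handling of the injected animals or arrays cannot be told apart from injection, since the labels name 0 batches. An effect of the injection itself may underlie the difference and remains open with handling.

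Lens genes were higher on the second ISOX DUAL array, where the median over 21 lens genes lay 1.24 log2 above the PBS mean. Lens genes that are not crystallins had a median 0.303 log2 above it, only just over the bound of 0.3 set beforehand, and beyond the -0.24 to 0.08 of the other 9 arrays. Mip was at 7.59 there and at 6.01 to 6.37 elsewhere and the crystallin gene Cryaa was at 11.75. Bfsp1 (6.21) and Bfsp2 (6.38) were also highest there. Lim2 (5.96), Gja3 (5.82), Lgsn (5.44) and Lctl (5.24) lay below that array's negative control median of 6.07. Gja3 was at 5.63 and 5.82 and Lgsn at 5.40 and 5.42 with PBS, so the median rests on weak signals. A crystallin response that accompanies reactive gliosis would also raise lens genes in uninjected OIR, where the list differed from untreated retina by -0.134 (-0.16 to -0.09). This argues against such a response to gliosis without an injection. Relative to untreated retina, lens scores were 0.10 and 0.32 with PBS and 0.42 on the first ISOX DUAL array. They were -0.16 and -0.09 in uninjected OIR. Lens tissue carried over in the dissection is a candidate explanation for the second ISOX DUAL array. Release from a lens touched by the needle and a crystallin response to the injection were not tested.

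Xist and Y-linked genes separated both day 7 arrays from all 8 day 17 arrays. Xist differed by -7.161 log2 between day 17 and day 7, with 11.83 and 11.62 at day 7 and 4.39 to 4.64 at day 17. Uty, Kdm5d and Eif2s3y were each lower on both day 7 arrays than on any day 17 array. Different sex of the animals is consistent with these values. Sex and age cannot be separated in the comparison of the 2 days, and the day 17 arrays are alike in these genes.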

How the results depend on the processing

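Counts by limma moved with the setting. The 115 genes of OIR against untreated retina became 12 with array weights, 0 with only those 2 groups in the fit, 352 at an unadjusted p under 0.05 with a 1.5-fold difference, 19 when uninjected and PBS-injected OIR were taken as 1 group, 0 for PBS-injected OIR against untreated retina, and 0 to 35 with 1 array of the groups compared left out (0 to 84 with any of the 10, which share the spread). An array left out is 1 of the groups compared unless any of the 10 is stated. The 0 genes of ISOX DUAL against PBS became 62 at an unadjusted p under 0.05 with a 1.5-fold difference and 0 to 1 with 1 array left out. The 1 gene of ISOX DUAL against uninjected OIR became 3 with array weights, 0 with the day 17 groups only, 0 with only those 2 groups, 185 at the unadjusted threshold and 0 to 7 with 1 array left out. The 0 genes of PBS against uninjected OIR became 2 with quantile normalization, 2 over protein-coding genes, 228 at the unadjusted threshold and 2 for both injected groups against OIR. The 4 genes of ISOX DUAL against untreated retina (2 higher, 2 lower) became 2 with quantile normalization (2 higher, 0 lower), 1 with median centring (1 higher, 0 lower), 8 with eBayes trend and robust options, 0 with array weights, 0 with the day 17 groups only, 11 over protein-coding genes, 0 with only those 2 groups, 453 at the unadjusted threshold and 0 to 6 with 1 array left out. The 2454 genes of day 17 against day 7 became 1111 with array weights, 345 with only those 2 groups and 1500 to 2227 with 1 array left out. With the replicate number as a block, counts were 134 for OIR against untreated retina, 5 for PBS against OIR, 1 for ISOX DUAL against OIR, 2 for ISOX DUAL against untreated retina and 0 for ISOX DUAL against PBS. With that pairing crossed for the injected groups, chosen after the data were seen, the counts were 215, 4, 5 and 53, in the same order of the first 4 comparisons, and 3 reverted genes. Lists called numbered 21 for OIR against untreated retina (7 with an estimated correlation, 9 by fry, 13 to 19 with 1 array left out), 10 for ISOX DUAL against PBS (1, 0, and 5 to 11), 18 for ISOX DUAL against OIR (3, 4, and 18 to 19), 18 for PBS against OIR (4, 8, and 15 to 18), 15 for ISOX DUAL against untreated retina (0, 5, and 12 to 16) and 11 for day 17 against day 7 (0, 12, and 10 to 11). Genes raised in OIR and lower with ISOX DUAL than OIR numbered 1, then 2 with array weights, 0 with the day 17 groups only, 89 at the unadjusted threshold and 0 with any of the 10 arrays left out, and with PBS as the control they numbered 0 throughout. The slope of 0.143 was 0.032 with array weights and 0.088 to 0.226 with 1 array left out. Directions of list means turned with 1 array left out for interferon genes in OIR against untreated retina (-0.060 to 0.265), for retinal ganglion cell (-0.529 to 0.023) and retinal pigment epithelium genes (-0.259 to 0.064) in ISOX DUAL against PBS, and for microglia (-0.376 to 0.043) and cholesterol genes (-0.28 to 0.033) in PBS against OIR, while for hypoxia targets in ISOX DUAL against PBS (0.0004 to 0.12) the direction against all other genes turned at 0.003. No named gene that passed in a comparison changed direction there, and of 106 pairs of a named gene and a comparison in which it did not pass, 18 did under some setting. A group left with 1 array is assumed to vary like the others. The cause of the differences between settings was not tested, and weights follow the unequal spread of the groups. Signal over background limits what weakly expressed genes can show, since at most 9.97% of transcript clusters exceeded the 95th percentile of the negative controls on an array.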

Other observations

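No hypothesis of its own was tested in this part, and the features below were picked after their values were seen.

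Retinal ganglion cell genes were lowest on 3 of the 4 injected arrays. Relative to untreated day 17 retina, the list score over 15 genes was -0.14 and -0.34 log2 in uninjected OIR, -0.83 and -0.28 with PBS and -0.64 and -0.97 with ISOX DUAL. Slc17a6 was at 8.96 and 8.93 in untreated day 17 retina, at 7.52 and 8.51 with PBS and at 7.83 and 7.04 with ISOX DUAL. Other lists were lower on these arrays too: with PBS and then ISOX DUAL, amacrine cell scores were -0.44, -0.20, -0.30 and -0.32, horizontal cell scores -0.39, -0.25, -0.27 and -0.28, and cholesterol gene scores -0.43, -0.12, -0.30 and -0.39. Rod genes stayed within 0.12 log2 of untreated retina on every day 17 OIR array. Cell cycle genes were higher on all 6 OIR arrays, with scores of 0.16 to 0.35, and immediate-early genes were higher in uninjected OIR (0.57 and 0.41) and between -0.07 and 0.02 on the injected arrays.

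The predicted genes Gm20810 and Gm21118 differed between the injected groups. Gm20810 was at 4.30 and 4.32 log2 on the ISOX DUAL arrays, at 7.09 and 5.75 on the PBS arrays, at 5.48 and 5.39 in uninjected OIR, at 5.79 and 4.90 in untreated day 17 retina, and at 4.28 and 4.34 at day 7. Gm21118 was at 4.47 and 4.45 with ISOX DUAL and at 7.30 and 5.88 with PBS. Except on the first PBS array, both genes lay below the median of each array's negative control probes. Neither passed the threshold against PBS, and near-identical copies of such genes can share probes, so their values are uncertain.

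Across all genes, the covariance of the OIR difference with the difference of ISOX DUAL from uninjected OIR was -0.0058, where simulations in which the injected groups had no change gave -0.0177.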
